A study of Mus musculus with 7 samples.

How the data were processed

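RNA was measured in 7 samples of sorted mouse bowel cells at embryonic day 17.5, 4 EYFP-positive and 3 EYFP-negative. Per the labels' protocols, cells of the whole bowel were separated by fluorescence-activated cell sorting, total RNA was extracted with Trizol, and biotin-labelled cDNA was made with a whole-transcriptome amplification kit for very small RNA amounts. The deposited values are log2 expression levels per probe set of an Affymetrix mouse gene array, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects background, brings arrays to a common distribution and summarises the probes of a set. Program versions, and whether all 7 arrays were normalized in 1 run, are not given in the sources used here. Amplification from small RNA amounts and quantile scaling can both compress differences, and with no detection calls a level near the floor cannot be told from background. Every sample column was matched to its sample by name, and 0 were left unmatched.

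The table held 35556 probe sets, of which 116 had the same value on all arrays to 6 decimals. The platform annotation paired 21789 of them with 1 gene symbol and 1621 with several, and 12146 were not listed in it. Probe sets with several genes or none were left out. Some genes of the lists are not analysed here. Entrez identifiers matched the GRCm38.p6 RefSeq gene table for 21698 probe sets, and no symbol differed between the tables. No genome coordinates are given, because the build of the array annotation was not stated. For the 998 genes with several probe sets, the one with the highest mean over the 7 arrays was used, and 1 second identifier of a symbol was left out, which gave 19938 genes.

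Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used. The design, the tests, 43 gene lists, 31 by symbol and 12 by gene family, and the rule for named genes were fixed before the data were examined. Groups were compared with lmFit and eBayes of limma with the group as the only term, p-values were adjusted over all genes by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Fold changes are differences of mean log2 values, YFP-positive minus YFP-negative, given with the standard error of the moderated fit. Lists with at least 3 measured genes were tested with limma camera at its preset inter-gene correlation of 0.01, two-sided and adjusted over the 43 lists, and again with the correlation estimated per list and with fry. Each list's counts are also given with p-values adjusted over the list alone. The fit was tested on simulated data for 19938 genes, with 50 genes changed at each size: it recovered 58% of 1.5-fold, 96% of 2-fold, 96% of 4-fold and 100% of 8-fold changes, with 10 false calls. The simulated noise was independent between genes and of the same spread in both groups. The real spread was not, with an SD of the myeloid list mean of 0.57 in YFP-positive and 0.17 in YFP-negative arrays. These shares therefore do not give the recovery in the real data.

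Named genes are the 12 with the largest log2 fold change in each direction among genes past the threshold with no overlap between the groups (unnamed and predicted loci left out), up to 4 members of each list with the largest change past the threshold, up to 2 that passed against most of their list, the extremes of each gene family, and 14 genes fixed whatever their values, of which 12 were analysed here. A gene named outside this rule is said to be chosen after its values were seen.

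The alternatives were eBayes with trend and robust options, arrays centred on their medians or quantile normalized again, the third of genes with the lowest mean left out, the mean of all probe sets of a gene, every probe set tested, array weights, a test against a fold of 1.5 (treat), the replicate number as a block, and each array left out in turn. After the data were seen, the mean of the intestinal epithelium list as a covariate and a fit without YFP-positive arrays 3 and 4 were added. Hox genes were first filtered on their level in at least 1 group (22 genes, rho -0.7235 with the paralog group). That filter depends on the change itself, and one on the mean of the groups left 16 genes with 1 of paralog groups 8 to 13 (rho -0.4672), so random lists matched on level were used in their place. Bright members of other lists were likewise first chosen by their YFP-negative level and then by the mean of the groups. The slope of the epithelium genes was first set against random lists matched on level, which do not share the correlation among those genes, and is now read by exact permutation of the arrays. Single arrays that stand apart were searched for with Dixon's gap ratio in the group of 4. Further lists for sympathetic and chromaffin cells, neutrophils, mast cells, MHC class II, natural killer and innate lymphoid cells, and neurexin ligands and adhesion scaffolds were written after the data were seen and are used only in the closing section.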

Results

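Gene expression was measured on 7 microarrays of cells sorted from the bowel of mouse embryos at embryonic day 17.5. The embryos carried Wnt1-Cre, a recombinase active in the neural crest, and a reporter that makes the yellow fluorescent protein EYFP once Cre has acted, so that neural crest cells and their descendants fluoresce. Fluorescence-activated cell sorting gave 4 EYFP-positive samples, the enteric neural crest-derived cells (ENCDC), and 3 EYFP-negative samples with the other cells of the bowel. ENCDC form the neurons and glia of the enteric nervous system (ENS), the nerve network of the bowel wall. The study asked which genes are enriched in ENCDC and could act late in ENS development. Over the tested genes the median level of an array lay between 5.87 and 5.92 on the log2 scale. The number of arrays limits the precision of every value. The labels do not say that the samples of a group came from separate animals or litters, so p-values measure only the spread between these samples. The values carry no detection call, so the level of a dim gene can be largely background and its fold change understated.

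Genes of neurons and glia had the largest differences in favour of ENCDC. Chrna3, a subunit of the nicotinic acetylcholine receptor of autonomic neurons, led with a level 34.4-fold higher in YFP-positive cells (log2 fold change 5.10 ± 0.22 SE, limma adjusted p = 3.41e-05). Its log2 level was 9.78 ± 0.29 (SD, n = 4) in YFP-positive and 4.68 ± 0.38 (SD, n = 3) in YFP-negative cells. The neuronal tubulin Tubb3 followed at 4.95 ± 0.29, then Fabp7, a fatty acid-binding protein of glia and progenitors, at 4.89 ± 0.27, the receptor tyrosine phosphatase Ptprz1 at 4.88 ± 0.12 and the neuronal RNA-binding protein Elavl4 at 4.69 ± 0.23 (log2 fold change ± SE). The rest of the 12 largest increases were Fstl5, the neuropeptide gene Gal, Gng3, Snap25, the adhesion molecule Chl1, Slc10a4 and Syt1, with log2 fold changes from 4.37 down to 4.24.

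Genes of blood-derived immune cells had the largest differences in favour of the EYFP-negative cells. S100a8, which encodes a calcium-binding protein of neutrophils and monocytes, was 39.6-fold lower in YFP-positive cells (log2 fold change -5.31 ± 0.85 SE, limma adjusted p = 0.00559). Stfa2 (-4.80 ± 0.51), the mast cell protease gene Mcpt2 (-4.61 ± 0.41), S100a9 (-4.50 ± 0.67) and the lysozyme gene Lyz2 (-4.37 ± 0.36) came next. Cd53, Cd52, Rgs1, Stfa3, Ms4a6b, Laptm5 and Gpr65 completed the 12 largest decreases, with log2 fold changes from -4.36 to -4.14.

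**Figure D1:**
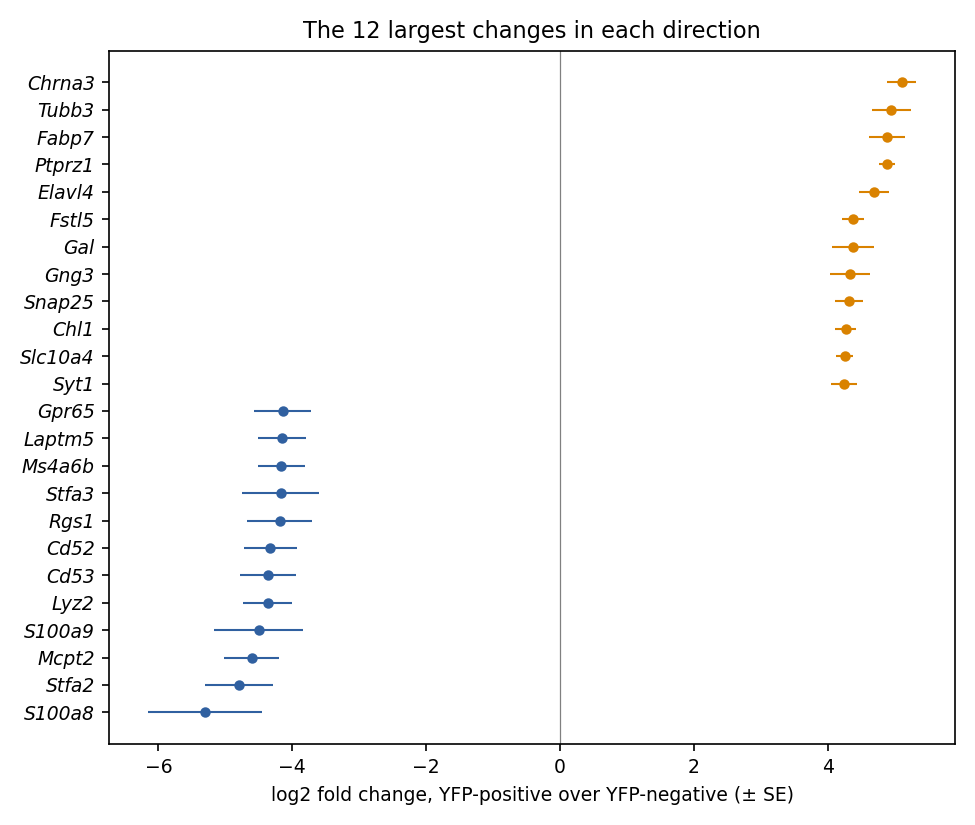
Log2 fold change of YFP-positive over YFP-negative cells (horizontal axis) for the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold. Points are limma estimates and bars their standard errors, from 4 YFP-positive and 3 YFP-negative arrays, and the values run from -5.31 for S100a8 to 5.10 for Chrna3.

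Over all 19938 genes tested, 3489 differed between the groups at a limma adjusted p under 0.05, of which 1672 were higher and 1817 lower in YFP-positive cells. At least 2-fold differences were found for 623 of the higher and 904 of the lower genes, at least 4-fold differences for 201 and 274, and at least 8-fold differences for 69 and 88. The ranges of the groups did not overlap for 3484 of the 3489 genes, and over all genes for 5368, where chance alone gives 5.71% of genes. Across arrays the correlation over genes was 0.913 to 0.951 between the groups, 0.984 to 0.994 among YFP-positive arrays and 0.980 to 0.992 among YFP-negative arrays, and the first principal component held 77.9% of the variance. Leaving out YFP-negative array 2 lowered the count of lower genes from 1817 to 1166, and a test against a 1.5-fold rather than any difference called 1027 genes.

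Of 43 gene lists fixed before the data were examined, 28 shifted as a set by limma camera with its preset correlation, 16 towards and 12 away from YFP-positive cells. With a correlation estimated per list, camera called 0 of the 43 at an adjusted p under 0.05, and 13 had an unadjusted p under 0.05, while fry, which asks whether the genes of a list move one way on balance, called 29. For the lists below, the adjusted p with an estimated correlation stands beside each shift.

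Regulators of ENS progenitors were higher in ENCDC almost throughout. Of 16 measured genes 14 rose and 0 fell, 15 and 0 adjusted over the list alone, with a median log2 fold change of 2.33 (limma camera adjusted p = 4.84e-16; adjusted p = 0.141 with an estimated correlation). Ret, the receptor tyrosine kinase for GDNF-family ligands, was 10.6-fold higher (3.40 ± 0.18), and L1cam (3.54 ± 0.25), the homeobox gene Hoxb5 (3.27 ± 0.10) and the T-box gene Tbx3 (2.83 ± 0.08) rose as well. The endothelin receptor gene Ednrb rose by 2.34 ± 0.10 and had a high level in both groups, 11.17 ± 0.17 (SD, n = 4) against 8.83 ± 0.08 (SD, n = 3). Sox10, a transcription factor of neural crest progenitors and glia, rose by 2.52 ± 0.15. Zeb2 (0.41 ± 0.13) and Insm2 (0.02 ± 0.05), the 2 members that did not pass, were chosen after their values were seen.

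Ligands that act on the ENS were more often lower than higher in ENCDC, and 15 of 28 did not pass. Of 28 measured ligand and matrix genes, 11 were lower and 2 higher in YFP-positive cells, 13 and 2 adjusted over the list alone, with a median log2 fold change of -0.30 (limma camera adjusted p = 0.00184; adjusted p = 0.266 with an estimated correlation). The signalling genes Bmp4 (-2.09 ± 0.35), Cxcl12 (-2.06 ± 0.32) and Edn3, the ligand of Ednrb (-1.66 ± 0.20), fell, and Bmp7 (1.68 ± 0.08) and the semaphorin gene Sema3c (1.37 ± 0.16) rose. Gdnf, the ligand of Ret, had a log2 fold change of -0.88 ± 0.27 and did not pass (limma adjusted p = 0.0717), nor did Nrtn at -0.17 ± 0.07 (limma adjusted p = 0.157). The count of lower ligands was 7 without YFP-negative array 1, without YFP-negative array 2 or without YFP-positive array 3.

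Among 30 receptors for those ligands, 8 were higher and 5 lower in ENCDC, 8 and 7 adjusted over the list alone. Erbb3, the neuregulin receptor of glial precursors (2.61 ± 0.13), and the Wnt receptor gene Fzd3 (2.48 ± 0.14) rose beside Ret, while Kit (-2.35 ± 0.38) and Fgfr2 (-1.34 ± 0.26) fell. The list had a median log2 fold change of -0.01 and a mean of 0.29, and camera, upward in sign, did not call it (adjusted p = 0.304; adjusted p = 0.369 with an estimated correlation), while fry called it upward (adjusted p = 1.04e-04). The median was 0.02 without YFP-positive array 1 and -0.02 without YFP-negative array 3. The 5 lower receptors became 2 without YFP-negative array 2, 4 without YFP-positive array 4 and 3 without any other array, and the call of Fgfr2 was lost without YFP-negative array 1 or 2.

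Genes linked to Hirschsprung disease, in which ENS precursors are missing from the distal bowel, went both ways. Of 19 measured, 8 were higher in ENCDC, among them L1cam, Ret, Sox10 and the neuregulin gene Nrg3 (2.58 ± 0.14), and 4 were lower, among them Edn3 and Sema3d (-1.23 ± 0.22), or 9 and 5 adjusted over the list alone. Limma camera called the list upward (adjusted p = 0.0121; adjusted p = 0.141 with an estimated correlation), with a median log2 fold change of 0.32. The median was 0.21 without YFP-positive array 1. Without YFP-negative array 1 or 2 the lower members numbered 2, and the list call was lost without YFP-positive arrays 3 and 4 together (adjusted p = 0.0811).

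Pan-neuronal genes rose nearly as a block. Of 28 measured, 27 rose and 0 fell, with a median log2 fold change of 3.27 (limma camera adjusted p = 2.76e-26; adjusted p = 0.141 with an estimated correlation), and 27 rose and 1 fell adjusted over the list alone. Tubb3, Elavl4, the G-protein subunit gene Gng3 (4.33 ± 0.30) and Snap25, a protein of the vesicle fusion complex (4.32 ± 0.20), had the largest values. Chgb, a secretory granule gene of neurons and endocrine cells, was chosen after its values were seen and stood at -0.74 ± 0.31 (limma adjusted p = 0.164), and passed as lower without YFP-negative array 3. Genes of synaptic vesicles and release rose in 19 of 23 cases and fell in 0, 20 and 1 adjusted over the list alone, with a median of 1.56 (limma camera adjusted p = 1.08e-12; adjusted p = 0.141 with an estimated correlation). Syt1 (4.24 ± 0.20), Syt11 (3.43 ± 0.15) and Snap91 (2.72 ± 0.14) rose beside Snap25.

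The pan-neuronal mean level differed among the YFP-positive arrays. It was 8.97 and 8.89 on YFP-positive arrays 1 and 2, and 8.54 and 8.41 on arrays 3 and 4, against 5.58 to 5.73 on the YFP-negative arrays. The mean level of the intestinal epithelium list went the other way, at 7.33 and 7.51 on arrays 1 and 2, and 8.16 and 8.31 on arrays 3 and 4. So did those of other non-neural lists, among them fibroblast and mesenchyme genes (6.84, 7.10, 7.54 and 7.68 on arrays 1 to 4), smooth muscle genes (7.59, 8.07, 8.56 and 8.92) and myeloid genes (5.36, 5.71, 6.30 and 6.61). Without arrays 3 and 4, an alternative chosen after seeing the data, 2684 genes differed, 1292 higher and 1392 lower. The epithelium, fibroblast, smooth muscle, myeloid and mesothelium means were all highest on arrays 3 and 4 within the group. Leaving these arrays out therefore lowers those lists in YFP-positive cells by the choice itself.

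**Figure D2:**
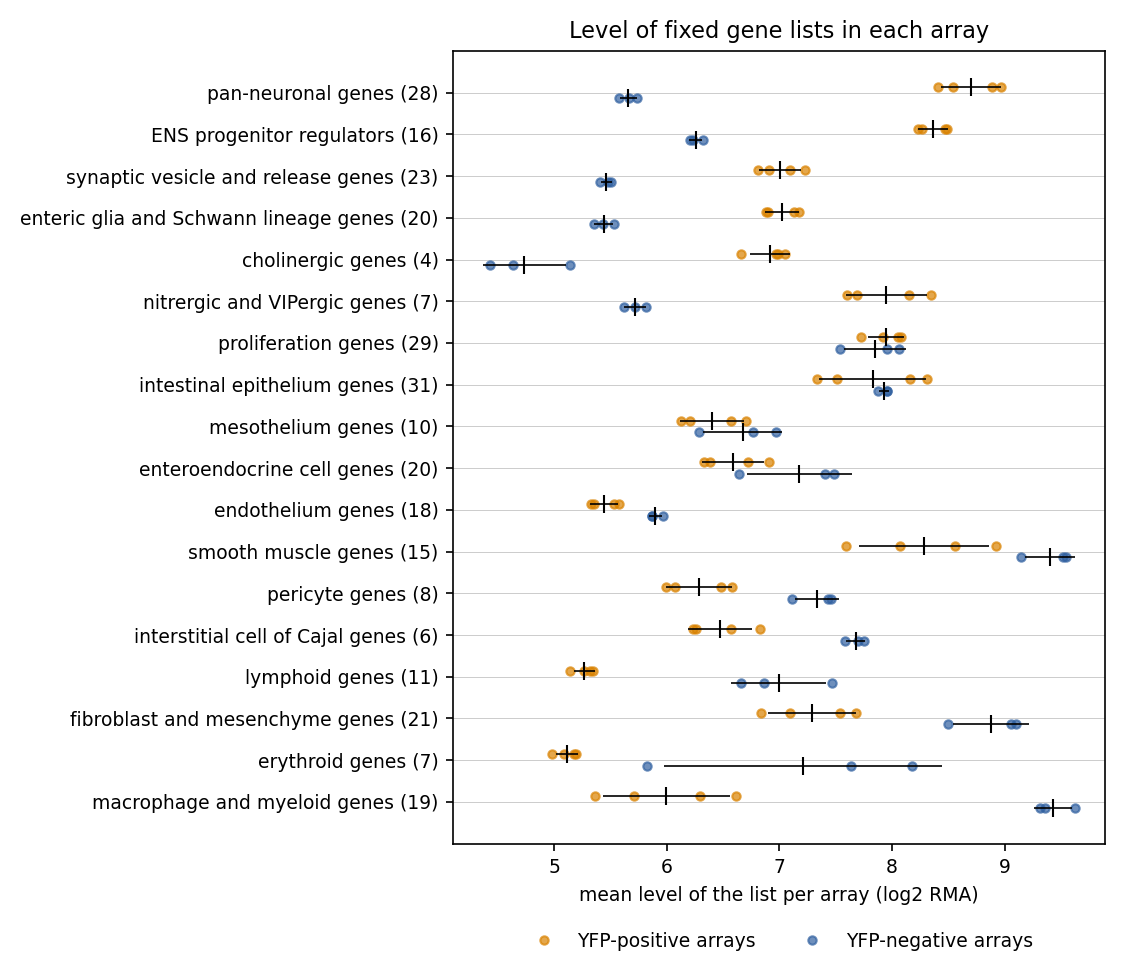
Mean log2 RMA level per array (horizontal axis) of 18 of the fixed gene lists, with the number of measured genes in brackets; circles are single arrays, 4 YFP-positive (orange) and 3 YFP-negative (blue), and black ticks with bars are group means ± SD. Pan-neuronal means lay at 8.41 or above on YFP-positive and at 5.73 or below on YFP-negative arrays, while the epithelium means of the YFP-positive arrays, 7.33 to 8.31, spanned those of the YFP-negative arrays.

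Ion channel genes that passed were mostly higher in ENCDC. Of 18 ligand-gated channel genes 11 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 1.60 (limma camera adjusted p = 4.17e-09; adjusted p = 0.141 with an estimated correlation). Chrna3, its partner subunit gene Chrnb4 (4.21 ± 0.19), the kainate receptor gene Grik2 (16.0-fold) and the AMPA receptor gene Gria2 (3.18 ± 0.14) rose, and the GABA receptor gene Gabra3 fell (-0.81 ± 0.13). Nicotinic receptor genes taken as a family had 6 of 16 members higher and 0 lower, also adjusted over the list alone, with Chrna3 the largest and Chrna4 (1.03 ± 0.10) the smallest increase that passed (limma camera adjusted p = 0.00541; adjusted p = 0.251 with an estimated correlation). Voltage-gated channel genes rose in 11 of 22 cases and fell in 0, 14 and 0 adjusted over the list alone, with a median of 0.51 (limma camera adjusted p = 1.81e-07; adjusted p = 0.141 with an estimated correlation). The sodium channel genes Scn3a (1.99 ± 0.29), Scn3b (1.97 ± 0.26) and Scn9a (1.53 ± 0.25) and the calcium channel gene Cacna1b (1.76 ± 0.13) were the largest of these. Of 87 potassium channel genes 16 were higher and 5 lower, 22 and 6 adjusted over the list alone, from Kcnt2 (2.41 ± 0.22) to Kcnj8 (-2.05 ± 0.29), and camera did not call the family (adjusted p = 0.0653; adjusted p = 0.369 with an estimated correlation), while fry did, upward (adjusted p = 0.0108). Camera called it without YFP-negative array 3 (adjusted p = 0.0487) or YFP-positive array 2 (adjusted p = 0.0427), and the 16 higher genes were 10 without YFP-negative array 1.

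Genes listed for the main transmitter classes of enteric neurons were mostly higher in ENCDC. All 4 measured cholinergic genes rose, also adjusted over the list alone: the vesicular acetylcholine transporter gene Slc18a3 by 3.34 ± 0.23, the choline transporter gene Slc5a7 by 2.43 ± 0.21, Ache by 1.98 ± 0.32 and Chat, the synthesizing enzyme, by 0.98 ± 0.14 (limma camera adjusted p = 1.05e-04; adjusted p = 0.141 with an estimated correlation). Of 7 genes of nitrergic and VIP neurons 5 rose and 0 fell, also adjusted over the list alone, with a median of 2.32 (limma camera adjusted p = 1.36e-06; adjusted p = 0.141 with an estimated correlation). Gal (4.37 ± 0.31), Vip (3.92 ± 0.40), the nitric oxide synthase gene Nos1 (2.81 ± 0.15) and Gfra1 (2.32 ± 0.10) were the largest. Gfra1, whose value is the list median, is a receptor gene and not a transmitter gene. Vip had a log2 level of 8.52 ± 0.79 (SD, n = 4) in YFP-positive cells.

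Of 23 genes of other enteric neuron subtypes 10 rose and 1 fell, 13 and 2 adjusted over the list alone, with a median of 0.40 (limma camera adjusted p = 1.83e-04; adjusted p = 0.204 with an estimated correlation). Cartpt (3.27 ± 0.30) and the neurturin receptor gene Gfra2 (1.53 ± 0.19) rose, as did the neuropeptide genes Tac1 (1.59 ± 0.42) and Grp (1.58 ± 0.36), and the mechanosensitive channel gene Piezo2 fell (-1.40 ± 0.27). The count of higher genes was 5 without YFP-negative array 1 or 2 and 6 without YFP-negative array 3 or YFP-positive array 2. The call of Tac1 (limma adjusted p = 0.0410) was lost without YFP-negative array 1 or any one YFP-positive array, with an adjusted p of up to 0.110. The call of Grp was lost without any one YFP-negative array or YFP-positive array 2, and that of Piezo2 without YFP-negative array 2.

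Catecholaminergic genes did not move together. Of 10 measured, the vesicular monoamine transporter gene Slc18a2 rose (1.97 ± 0.25), and the transcription factor genes Gata2 (-0.82 ± 0.21) and Gata3 (-1.53 ± 0.27), which are also active in blood cells, fell, for 2 higher and 2 lower adjusted over the list alone. The mean log2 fold change was 0.11, while the median, -0.05, and the camera direction were negative, and the list was not called (limma camera adjusted p = 0.778; adjusted p = 0.882 with an estimated correlation). The median was -0.08 without YFP-positive array 1 and -0.03 without YFP-positive array 3 or YFP-negative array 3. Dbh and Th, the enzymes of noradrenaline and dopamine synthesis, were chosen after their values were seen and did not pass. Dbh had a level of 7.10 on YFP-positive array 1 and 5.32 to 5.71 on the others, and Th 6.69 against 4.64 to 5.02. Leaving out YFP-positive array 1 raised the count of higher members from 1 to 2, and leaving out YFP-positive array 2, 3 or 4 or YFP-negative array 2 or 3 lowered the count of lower members from 2 to 1. The call of Gata2 was lost in the same 5 fits (adjusted p of up to 0.140).

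Genes of enteric glia and the Schwann lineage were higher in ENCDC or did not pass. Of 20 measured, 13 rose and 0 fell, 14 and 1 adjusted over the list alone, with a median log2 fold change of 1.45 (limma camera adjusted p = 1.24e-09; adjusted p = 0.141 with an estimated correlation). Fabp7 was followed by the cadherin gene Cdh19 (4.15 ± 0.25), the glial calcium-binding protein gene S100b (3.31 ± 0.26) and Ttyh1 (2.83 ± 0.19). Gfap, an intermediate filament gene of mature glia that was chosen after its values were seen, had a log2 fold change of 0.11 ± 0.15.

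Transcription factors of enteric neurons rose in 18 of 29 cases and fell in 1, 18 and 3 adjusted over the list alone, with a median log2 fold change of 0.75 (limma camera adjusted p = 1.78e-08; adjusted p = 0.141 with an estimated correlation). Tbx3, the distal-less homeobox gene Dlx1 (2.61 ± 0.18), Sox11 (2.21 ± 0.08) and Myt1 (2.12 ± 0.08) rose most. The homeobox gene Meis2 fell (-1.99 ± 0.32). The count of lower members was 3 without YFP-positive array 1 and 2 without YFP-positive array 3 or YFP-negative array 1.

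Hox genes, which mark position along the body axis, split by paralog group. In groups 1 to 5, 10 of 14 genes were higher in ENCDC and 0 lower, with a median log2 fold change of 0.90, and in groups 8 to 13, 0 were higher and 10 of 18 lower, with a median of -0.52. Between them, in groups 6 and 7, 2 of 5 were higher and 1 lower. Hoxb5 had the largest increase (3.27 ± 0.10) and Hoxc6 the largest decrease (-1.46 ± 0.16). Over the 37 measured Hox genes 12 were higher and 11 lower, 13 and 12 adjusted over the list alone. The family had a mean log2 fold change of 0.19 and a median of -0.01, and camera, upward in sign, did not call it (adjusted p = 0.530; adjusted p = 0.605 with an estimated correlation), while fry called it upward (adjusted p = 3.92e-04). Without any one YFP-negative array or YFP-positive array 4 the median was above 0, by 0.01 or less, and without YFP-negative array 2 the lower genes numbered 7, of which 6 were of groups 8 to 13.

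**Figure D3:**
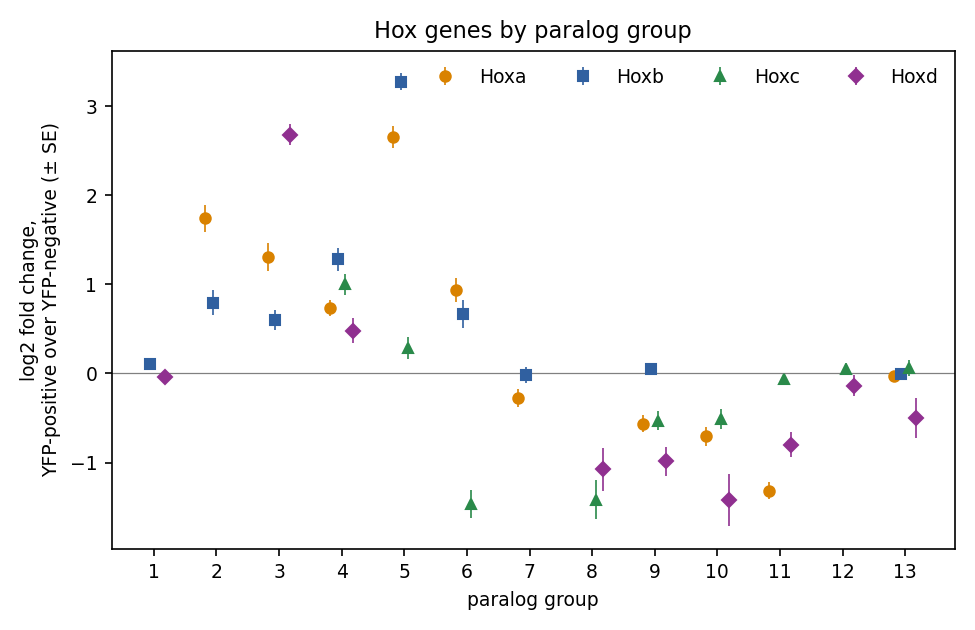
Log2 fold change of YFP-positive over YFP-negative cells (vertical axis) for 37 Hox genes by paralog group (horizontal axis, with the 4 clusters offset slightly), where points are limma estimates and bars standard errors from 4 and 3 arrays. No gene of groups 1 to 5 passed as lower and no gene of groups 8 to 13 passed as higher, and the values run from -1.46 for Hoxc6 to 3.27 for Hoxb5.

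Axon guidance receptors and adhesion molecules rose in 13 of 26 cases and fell in 4, also adjusted over the list alone, with a median log2 fold change of 0.47 (limma camera adjusted p = 1.83e-04; adjusted p = 0.141 with an estimated correlation). The cell adhesion genes Chl1 (4.26 ± 0.15), Ncam2 (3.62 ± 0.20) and Nrcam (2.87 ± 0.18) and the N-cadherin gene Cdh2 (3.47 ± 0.15) rose, and the Eph receptor genes Epha3 (-1.55 ± 0.27) and Ephb1 (-1.04 ± 0.17) fell. Among 34 protocadherin genes 7 rose and 2 fell, 9 and 2 adjusted over the list alone, from Pcdh15 (4.01-fold higher) to Pcdh18 (-1.66 ± 0.18), with a median of 0.32 (limma camera adjusted p = 0.00516; adjusted p = 0.360 with an estimated correlation). Lower protocadherin genes numbered 1 without YFP-negative array 2, and the median was 0.18 without YFP-negative array 3. Of 20 semaphorin genes 4 were higher and 4 lower, 5 and 4 adjusted over the list alone, from Sema3c (1.37 ± 0.16) to Sema5a (-1.71 ± 0.24), with no shift called (limma camera adjusted p = 0.559; adjusted p = 0.802 with an estimated correlation). Higher semaphorin genes numbered 2 without YFP-negative array 2.

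Macrophage and myeloid genes had the lowest median of the 43 lists, and lymphoid genes were lower in ENCDC by less. All 19 macrophage and myeloid genes were lower, also adjusted over the list alone and without any one array, with a median log2 fold change of -3.29 (limma camera adjusted p = 2.19e-18; adjusted p = 0.141 with an estimated correlation). S100a8, S100a9, Lyz2 and Laptm5 fell most, and Ptprc, the pan-leukocyte antigen CD45, fell by 3.85 ± 0.42 on the log2 scale. Mean myeloid levels were 5.36, 5.71, 6.30 and 6.61 on YFP-positive arrays 1 to 4 and 9.31 to 9.62 on the YFP-negative arrays. Of 11 lymphoid genes 9 were lower and 0 higher, 10 and 0 adjusted over the list alone, with a median of -1.53 (limma camera adjusted p = 1.78e-08; adjusted p = 0.141 with an estimated correlation), led by the interleukin receptor gene Il7r (-4.01 ± 0.32), Cd3g (-2.55 ± 0.27), Cd79b (-2.31 ± 0.23) and Ltb (-1.88 ± 0.26). Erythroid genes had a median of -1.91 over 7 members (limma camera adjusted p = 0.00735; adjusted p = 0.270 with an estimated correlation), but only Alas2, the haem synthesis enzyme of red cells, passed (-3.59 ± 0.98, limma adjusted p = 0.0475), and 3 were lower adjusted over the list alone. That call was lost without YFP-negative array 2 or 3 or any one YFP-positive array (adjusted p of up to 0.163). No member passed without YFP-negative array 2 or any one YFP-positive array, and 3 members passed without YFP-negative array 1, whose Alas2 level was 6.90 against 10.33 and 11.50 on the other YFP-negative arrays.

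Mesenchymal cell genes were lower in ENCDC as well. Fibroblast and mesenchyme genes fell in 18 of 21 cases and rose in 0, 20 and 0 adjusted over the list alone, with a median log2 fold change of -1.76 (limma camera adjusted p = 1.96e-11; adjusted p = 0.226 with an estimated correlation). The transcription factor genes Tcf21 (-2.68 ± 0.38) and Osr1 (-2.46 ± 0.35) and the matrix genes Dpt (-2.42 ± 0.37) and Lum (-2.30 ± 0.37) fell most, and the count of lower genes was 11 without YFP-negative array 2. Collagen genes were lower in 14 of 44 cases and higher in 4, 17 and 4 adjusted over the list alone, from Col6a1 (-1.86 ± 0.37) to Col18a1 (1.07 ± 0.12), with a median of -0.14 (limma camera adjusted p = 8.39e-04; adjusted p = 0.360 with an estimated correlation). Without YFP-negative array 2 or 1 the lower collagen genes numbered 6 and 7, and 7 without YFP-positive array 2 and 9 without YFP-positive array 1 or 4. The call of Col6a1 was lost without YFP-negative array 1 or 2 or YFP-positive array 2 (adjusted p of up to 0.0662).

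Smooth muscle genes were lower in ENCDC too, but with calls that hung on single arrays. Of 15 measured, 7 fell and 0 rose, and 14 fell adjusted over the list alone, with a median log2 fold change of -1.09 (limma camera adjusted p = 1.46e-05; adjusted p = 0.360 with an estimated correlation). Myocd (-1.66 ± 0.34), Tagln (-1.61 ± 0.41), Synpo2 (-1.40 ± 0.29) and the actin gene Acta2 (-1.24 ± 0.31) were among them. Mean levels of the list were 7.59, 8.07, 8.56 and 8.92 on YFP-positive arrays 1 to 4, against 9.15 to 9.55 on the YFP-negative arrays. The 7 lower genes were 0 without YFP-negative array 1, YFP-negative array 2 or YFP-positive array 2, 3 without YFP-positive array 1 or 3, 12 without YFP-positive arrays 3 and 4 together, and 13 with the epithelium mean as a covariate. With the arrays left out in turn, Acta2 passed only without YFP-positive array 4 (adjusted p of up to 0.121). The calls of Myocd, Tagln and Synpo2 were lost without YFP-negative array 1 or 2 or YFP-positive array 2 (adjusted p of up to 0.0710, 0.131 and 0.0716). That of Myocd was lost also without YFP-negative array 3 and that of Tagln without YFP-positive array 3.

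Interstitial cells of Cajal, the pacemaker cells of the bowel wall, share Kit with mast cells. Kit (-2.35 ± 0.38), Thbs4 (-1.84 ± 0.29), Prkcq (-1.65 ± 0.16) and the chloride channel gene Ano1 (-1.52 ± 0.25) were the 4 of 6 genes of their list that fell, with 1 higher and 4 lower adjusted over the list alone (median -1.58, limma camera adjusted p = 0.00704; adjusted p = 0.174 with an estimated correlation). Pericyte genes fell in 6 of 8 cases, also adjusted over the list alone, with Kcnj8 (-2.05 ± 0.29), Abcc9 (-1.75 ± 0.30), Pdgfrb (-1.67 ± 0.24) and Rgs5 (-1.65 ± 0.32) the largest (median -1.27, limma camera adjusted p = 0.00135; adjusted p = 0.251 with an estimated correlation). Without YFP-negative array 1 or 2, 3 pericyte genes passed and Rgs5 did not. Of 18 endothelium genes 5 fell and 1 rose, 10 and 2 adjusted over the list alone (median -0.32, limma camera adjusted p = 4.41e-04; adjusted p = 0.266 with an estimated correlation). Pecam1, the adhesion molecule CD31, fell by 1.74 ± 0.18 on the log2 scale, with Eng at -1.55 ± 0.15 and Emcn at -0.80 ± 0.17, and the VEGF receptor gene Kdr rose by 0.86 ± 0.09. The 5 lower endothelium genes were 2 without YFP-positive array 1 or 3 and 3 without YFP-positive array 2 or YFP-negative array 3. The 1 higher became 2 without YFP-negative array 1. The call of Emcn was lost without YFP-positive array 1, 2 or 3 or YFP-negative array 1 or 3.

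No difference between the groups was detected for epithelial genes as a list. None of 31 intestinal epithelium genes passed, also adjusted over the list alone, so that limma called 0 of them at an adjusted and 6 at an unadjusted p under 0.05. The median log2 fold change was -0.10 (limma camera adjusted p = 0.425; adjusted p = 0.882 with an estimated correlation; fry adjusted p = 0.788). That median was 0.06 without YFP-positive array 1 and -0.03, -0.17 and -0.35 without YFP-positive array 2, 3 or 4. Epcam, an adhesion molecule of epithelia, had a log2 fold change of 0.15 ± 0.23 (limma adjusted p = 0.717). Its list had a mean level of 7.83 ± 0.48 (SD, n = 4) in YFP-positive cells, with a range of 7.33 to 8.31, and of 7.93 ± 0.04 (SD, n = 3) in YFP-negative cells. Without YFP-positive array 4 camera called the list downward (adjusted p = 0.0362), as it did without YFP-positive arrays 3 and 4 together (adjusted p = 9.14e-06), where 8 of its genes were lower. Without YFP-negative array 3, 1 was lower. Of 20 enteroendocrine cell genes 3 fell and 2 rose, 7 and 2 adjusted over the list alone (median -0.78, limma camera adjusted p = 0.0239; adjusted p = 0.547 with an estimated correlation; fry adjusted p = 0.248). The hormone gene Gip (-2.55 ± 0.56) and the transcription factor gene Neurog3 (-1.28 ± 0.18) fell, and Scg5 (2.36 ± 0.26) and Insm1 (1.52 ± 0.18), which neurons also express, rose. The 3 lower genes were 1 without YFP-negative array 1, YFP-negative array 2 or YFP-positive array 3 and 9 without YFP-negative array 3. The call of Gip was lost without YFP-negative array 1 or 2 or YFP-positive array 1 or 3. Camera's call of the list was lost without YFP-negative array 1 (adjusted p = 0.100) or 2 (adjusted p = 0.115) and with the third of genes with the lowest mean left out (adjusted p = 0.125).

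Mesothelium genes, with 1 of 10 lower and 0 adjusted over the list alone, were not called (median -0.24, limma camera adjusted p = 0.158; adjusted p = 0.727 with an estimated correlation). The median was -0.42 without YFP-negative array 3 or YFP-positive array 3, -0.37 without YFP-positive array 4, -0.13 without YFP-positive array 1 and -0.16 without YFP-positive array 2. The lower gene, Wt1 (-0.75 ± 0.20), lost its call without YFP-negative array 1 or 2 or YFP-positive array 1, 2 or 4, and camera called the list downward without YFP-negative array 3 (adjusted p = 0.0115), where 2 genes were lower, and without YFP-positive arrays 3 and 4 together (adjusted p = 0.0147). Of 48 keratin genes 1, Krt80 (-0.79 ± 0.13), was lower, and of 23 claudin genes 1, Cldn22 (0.90 ± 0.09), was higher, in both cases also adjusted over the list alone. Neither family was called (limma camera adjusted p = 0.983 and 0.838; adjusted p = 0.993 and 0.901 with an estimated correlation), and in each the median and mean, 0.01 and -0.02 for keratins and 0.01 and -0.06 for claudins, differed in sign. The keratin median was -0.01 without YFP-negative array 2 or YFP-positive array 3, and the claudin median -0.02 without YFP-negative array 2 or YFP-positive array 4 and -0.03 without YFP-positive array 3. One more keratin gene was higher without YFP-negative array 1. The claudin counts were 2 higher without YFP-positive array 2, and 1 lower without YFP-negative array 2 or 3.

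No difference was detected for proliferation genes. Of 29 measured, 0 passed in limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05, with a median log2 fold change of 0.10 (limma camera adjusted p = 0.426; adjusted p = 0.882 with an estimated correlation; fry adjusted p = 0.741). The median was 0.00 without YFP-negative array 2, 0.17 without YFP-negative array 1 or YFP-positive array 3 and 0.19 without YFP-negative array 3. Stress genes that cell dissociation can induce were lower in ENCDC in 9 of 20 cases and higher in 1, 14 and 1 adjusted over the list alone (median -0.64, limma camera adjusted p = 5.84e-06; adjusted p = 0.222 with an estimated correlation). Gadd45b (-1.56 ± 0.31), Atf3 (-1.54 ± 0.15), Btg2 (-1.44 ± 0.17) and Dusp1 (-1.31 ± 0.12) fell and Fosb rose (0.48 ± 0.07). Without YFP-negative array 2, 5 fell and Gadd45b did not pass (adjusted p = 0.0625).

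Cholesterol synthesis genes rose in 3 of 15 cases and fell in 0, 5 and 0 adjusted over the list alone: Fdft1 (0.82 ± 0.16), Hmgcs1 (0.65 ± 0.15) and Lss (0.37 ± 0.09) (median 0.37, limma camera adjusted p = 0.00546; adjusted p = 0.531 with an estimated correlation; fry adjusted p = 0.117). Without YFP-negative array 1 or 3 or YFP-positive array 2, 1 gene of the list passed. The median was 0.23 without YFP-positive array 3. Lss was also lost without YFP-negative array 2 and Hmgcs1 without YFP-positive array 1 or 3. The list call was lost without YFP-positive arrays 3 and 4 together (adjusted p = 0.0612). Of 14 hypoxia and glycolysis genes 3 fell, also adjusted over the list alone, the glucose transporter gene Slc2a1 (-1.19 ± 0.30), Egln3 (-0.79 ± 0.20) and Hk2 (-0.74 ± 0.20), and the list was not called (limma camera adjusted p = 0.304; adjusted p = 0.836 with an estimated correlation). They numbered 0 without YFP-negative array 2 or YFP-positive array 1, 2 or 4, and 1 without YFP-negative array 1, and Slc2a1 was also lost without YFP-negative array 3. Among 73 oxidative phosphorylation genes 3 fell and 1 rose, also adjusted over the list alone, from Cox6b2 (-1.28 ± 0.13) to Cox8b (1.80 ± 0.26) (limma camera adjusted p = 0.214; adjusted p = 0.841 with an estimated correlation). Without YFP-negative array 3, 7 fell and camera called the list downward (adjusted p = 0.00464), and 1 fell without YFP-negative array 1 or 2. Of 57 cytosolic ribosomal protein genes limma called 0, also adjusted over the list alone, and 2 had an unadjusted p under 0.05, with a median of -0.04 (limma camera adjusted p = 0.184; adjusted p = 0.772 with an estimated correlation; fry adjusted p = 0.321), and camera called them downward without YFP-negative array 3 (adjusted p = 0.0317).

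Zinc finger genes with a Zfp symbol rose in 38 of 317 cases and fell in 6, 28 and 4 adjusted over the list alone, from Zfp536 (2.78 ± 0.16) to Zfp36 (-1.16 ± 0.11), with a median of 0.10 (limma camera adjusted p = 0.00184; adjusted p = 0.360 with an estimated correlation). The higher genes numbered 16 without YFP-negative array 2, 20 without YFP-positive array 2 and 25 without YFP-positive array 1, 3 or 4, and the lower ones 3 without YFP-negative array 2. Of 1015 olfactory receptor genes 5 were higher and 0 lower, and 0 adjusted over the list alone, from Olfr224 (0.43 ± 0.10) to Olfr695 (0.24 ± 0.06) by the size of the log2 fold change, and the family was not called (limma camera adjusted p = 0.426; adjusted p = 0.843 with an estimated correlation). The call of Olfr695 was lost without any one array, that of Olfr224 without any one array other than YFP-positive array 3. The count of higher genes was 1 without YFP-negative array 2 or YFP-positive array 2 or 4, 2 without YFP-positive array 1 and 3 without YFP-negative array 1 or 3. Without any one YFP-negative array or YFP-positive array 1 or 3, 1 or 2 genes were lower. Camera called the family upward without YFP-negative array 3 (adjusted p = 0.0487). Of 4 sex-linked genes 0 passed in limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (limma camera adjusted p = 0.838; adjusted p = 0.882 with an estimated correlation; fry adjusted p = 0.788). The mean level of the sex-linked list ranged from 5.13 on YFP-negative array 1 to 7.69 on YFP-positive array 4. These tests compare the groups only and do not show that the arrays are alike in sex.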

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

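The search for single arrays that stand apart was planned, and none of the tests in this part was chosen after the results were seen. Among 181 named genes and list means tested in the 4 YFP-positive arrays, 5 had 1 array far from the other 3. This is a smaller share than the 1 in 20 or so that chance gives, so none of them is set apart from chance. Dlx1 had a log2 level of 7.99 on YFP-positive array 2 and 7.45 to 7.51 on the others. Gria2 stood at 7.29 on array 2 against 6.81 to 6.89, and Cox6b2 at 7.33 on array 2 against 6.88 to 6.94. The endothelial gene Emcn was 4.76 on YFP-positive array 4 and 4.34 to 4.37 elsewhere in the group. Col18a1 was 6.89 on array 4 and 7.19 to 7.22 on the others. The 5 genes belong to 5 different lists, and the list means of all 43 lists kept within the limit of the test.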

How the results depend on the processing

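Of the settings here, the covariate and the fit without YFP-positive arrays 3 and 4 were chosen after seeing the data. The test against a fold of 1.5 called 1027 genes in place of 3489, 469 higher and 558 lower, 556 of them lower by at least 2-fold. With an estimated correlation per list, 0 of the 28 list calls held, with a smallest adjusted p of 0.141. Leaving out each array in turn gave 2368 to 3337 genes, 1202 to 1452 higher and 1166 to 1890 lower, 567 to 643 higher and 734 to 935 lower by at least 2-fold, and 27 to 33 lists, with the lowest count of lower genes, 1166, without YFP-negative array 2. The cause was not tested for any of these changes. Of the 135 named genes that passed, 112 passed in all 7 of these fits and 23 lost their call in at least 1. Other settings stayed within 1.5 times of each count: 3469 genes with trend and robust options, 3517 without the dimmest genes, 3542 with mean probe sets, 3643 over every probe set, 3699 after centring, 3870 after quantile normalization, 4176 with array weights, 3626 with the covariate and 2684 without YFP-positive arrays 3 and 4. No named gene and no list changed direction past the threshold under any setting in which it was compared. Lists were not tested with trend and robust options, after quantile normalization, over every probe set, with array weights or against a fold of 1.5. Named genes were not compared over every probe set or against a fold of 1.5. The replicate numbers share no label of litter or sort, and the deviations of same-numbered arrays did not correlate (r across genes of 0.01, -0.09 and 0.04), while YFP-positive array 2 correlated best with YFP-negative array 1 (0.27), so the numbers are not read as pairs. With the replicate number as a block, 2509 genes passed, 1245 higher and 1264 lower, 2270 of them among the 3489, and 28 lists. All 43 lists kept their camera result, while 19 named genes lost their call and 119 did not change. Lower collagen genes numbered 5 in place of 14 and lower fibroblast genes 12 in place of 18. Of the cholesterol synthesis genes 0 passed in place of 3.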

Other observations

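The lists in this part, the tests on epithelial genes, the test of neuron share and both tests on Hox genes were chosen after the data were seen. Markers of further immune cells were mostly lower in YFP-positive cells. Their lists were written with some of the genes already seen (S100a8, S100a9, Stfa2, Stfa3, Mcpt2 and Kit) and are therefore given without a list test. S100a8 and S100a9 also belong to the myeloid list and Kit to that of interstitial cells of Cajal. These lists are thus not separate evidence of further cell types. All 6 MHC class II genes were lower in YFP-positive cells, with a median log2 fold change of -3.27, led by Cd74, the invariant chain (-3.97 ± 0.41). Mast cell genes fell in 8 of 11 cases (median -2.35), among them the protease genes Mcpt2 and Cpa3 (-3.65 ± 0.19). Neutrophil genes fell in 9 of 13 cases (median -2.83) and natural killer and innate lymphoid genes in 8 of 9 (median -2.09), led by Klrd1 (-3.93 ± 0.28) and the granzyme gene Gzma (-3.77 ± 0.31). Neurexin ligand and adhesion scaffold genes rose in 10 of 12 cases and fell in 0 (median 0.74), with the scaffold gene Dlg2 (3.67 ± 0.10) and the adhesion genes Slitrk6 (2.45 ± 0.26) and Lrrtm1 (1.70 ± 0.21) the largest.

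Erythroid genes and sex-linked genes varied within the groups. The mean erythroid level was 5.82, 7.64 and 8.18 on YFP-negative arrays 1 to 3 and 4.99 to 5.20 on the YFP-positive arrays. The Y-linked gene Uty had a log2 level of 2.77 on YFP-positive array 2 and 3.48 on YFP-negative array 1, 4.54 on YFP-positive array 1 and 5.85 to 6.51 on the other 4 arrays. Xist, transcribed from the inactive X chromosome, was 10.58, 10.20 and 10.56 on the first 3 of these and 8.98 to 9.39 on the others.

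Of the 35 splits of the 7 arrays into 4 and 3, 1 gave as many genes past the threshold as the real grouping, which is the real one itself with 3489 genes, and the highest of the others gave 0. The share is thus 1 in 35, the smallest these splits can give. It holds only for independent samples, which the labels do not establish. Each of the other splits mixes the 2 sorted groups.

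No difference between the sorts was detected for intestinal epithelium genes, with 0 of 31 passing, while the myeloid, fibroblast and smooth muscle lists were called lower. The epithelium means of YFP-positive arrays 1 and 2 (7.33 and 7.51) lay below the YFP-negative means (7.88 to 7.96). Those of arrays 3 and 4 (8.16 and 8.31) lay above them. Of 15 smooth muscle genes 7 were lower, a count that fell to 0 in some fits with 1 array left out. The epithelium median lay above that of the nearest of these lists, smooth muscle, by 0.996 (95% bootstrap interval over genes 0.70 to 1.38). That gap restates the pattern that prompted it, so it is no separate evidence against even carry-over of all EYFP-negative cells. The medians of mesothelium (-0.24) and endothelium (-0.32) lay nearer. Compression of bright probe sets was examined in 32 bright members of the myeloid, fibroblast and smooth muscle lists. These lay at or above the epithelium's median level, by the mean of the groups, with a median log2 fold change of -1.83 (-2.46 to -1.63). Their lists had already been called lower, so this value largely restates that result. It shows only that bright probe sets can differ between the groups, and a partial compression is not excluded. Production by the neural crest cells themselves stays open: over the 4 YFP-positive arrays the epithelium genes had a mean slope of -1.77 on the pan-neuronal mean, which restates the levels that prompted it and goes with a rise of the fibroblast, smooth muscle and myeloid means over the same arrays, and its exact permutation p of 0.0833 is the smallest that 24 orders of 4 arrays can give. Also open, as a hypothesis that no unsorted sample here can test, is that epithelial cells may have entered the EYFP-positive gate as doublets or by autofluorescence, or may have been lost from the EYFP-negative sort. Without YFP-positive arrays 3 and 4, where these genes were highest, 8 of the 31 were lower in YFP-positive cells. This fit was chosen after the data were seen, so the count follows from the choice of arrays.

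The mean of the catecholaminergic list was 5.93 on YFP-positive array 1 against 5.27 to 5.39 on the other 3, a gap within the limit of the planned test for single arrays, and Th and Dbh, chosen after their values were seen, were at 6.69 and 7.10 there, while Slc18a2, the member called higher, was 8.11 on array 1 and 8.26 on array 2. A larger share of neurons in that sample stays open: the list exceeded YFP-positive array 2 by 0.579 more than the pan-neuronal list did (0.656 against 0.077), but against arrays 3 and 4 this excess was 0.15 and -0.02, and single arrays give no spread between samples. Sympathetic neurons or chromaffin cells carried over from outside the bowel wall may be the source: 10 further genes of these cells, 3 higher, 3 lower and not called between the groups (limma camera adjusted p = 0.569; adjusted p = 0.578 with an estimated correlation), were higher on array 1 by 0.0489, at percentile 73.0 of random lists (-0.18 to 0.16). That value lies between the bounds set for and against, so this explanation stays open, as does a true difference between samples in the catecholaminergic cells of the bowel. The pattern rests on 1 array and on part of the list.

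Of the Hox genes, 10 of 14 in paralog groups 1 to 5 were higher and 10 of 18 in groups 8 to 13 lower in ENCDC. Over all 37 genes the log2 fold change fell with the paralog group (Spearman's rho -0.5864, Pearson's r -0.54, permutation p = 0.00022, across genes, which are not independent replicates). Among the 16 genes bright in the mean of the groups, with 1 of groups 8 to 13, rho was -0.4672 (permutation p = 0.0695). A fall in both sets had been set as the sign of a difference in axial origin, so that sign was not met. Groups 1 to 5 exceeded groups 8 to 13 by a mean of 1.76 on the log2 scale. In 95% of pairs of random lists matched on level, this difference lay between -0.45 and 0.52. Of the 18 genes of groups 8 to 13, 10 were lower (6 without YFP-negative array 2), against 0 to 4 in such lists. Level alone gave no such split, but the cut between groups was set after the pattern was seen. With 1 bright gene in groups 8 to 13 by the mean of the groups, dim probe sets are not excluded. A difference in axial origin may explain the order, since most ENCDC descend from vagal neural crest, which expresses low paralog groups. The EYFP-negative sort mixes cells of other origins, blood-derived ones among them. A difference in axial origin is a hypothesis that no sample here can test, and the correlation over all genes restates the pattern that prompted it. Cross-hybridization between paralogs was not tested.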
